A study of Mus musculus with 12 samples.

How the data were processed

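Messenger RNA was measured by RNA sequencing in 12 colon libraries of C57BL/6 mice that carry the ApcMin/+ mutation. The genotypes were Cul4bWT (WT) and Cul4bΔIEC (KO). The sample titles mark each library as T or N, and the design text names adenoma and adjacent normal tissue; T was read as adenoma and N as adjacent normal colon. Each genotype and tissue had 1 library at each of 3, 4 and 5 months of age, so each of the 4 groups held 3 libraries and the ages served as replicates (replicate 1 is 3 months, replicate 2 is 4 months and replicate 3 is 5 months). The labels do not say that the libraries came from separate animals.

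Values were deposited as FPKM (fragments per kilobase of gene, scaled by a library total) for 52636 Ensembl genes, in 1 table for the 8 libraries of 3 and 4 months and another for the 4 libraries of 5 months. A deposited gene length column, in bases (a unit other than FPKM), was used to convert FPKM into read steps. Per the submitters' processing notes, the authors used the mm10 genome, StringTie, featureCounts 1.5.0-p3 and DESeq2; the aligner and the annotation release are not given in the sources used here. In each library, FPKM times gene length was a whole number of equal steps in 100% of values (tolerance 0.01 of a read), so reads per gene could be recovered. The step implied a library total of 0.720 to 1.30 times the reads in genes, proportional to median-of-ratios size factors (0.719 to 1.35) computed within each table. The deposited FPKM were thus scaled by size factors, separately in each table. Levels from different tables are therefore on separate scales, and the age term of the model keeps each difference between groups within a table.

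Reads assigned to genes were 18263611 to 25321931 per library (median 21183824). A count of 3 reads corresponds to 0.0524 to 0.100 FPKM for a gene of 2 kilobases, depending on the library. Such floors cover counting error only, since reads copied by PCR are not independent molecules.

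Expression was compared with limma 3.58.1 in R 4.3.3 (lmFit, then eBayes with an intensity trend) on log2(FPKM + 1), in a single model of all 12 libraries with group and age as terms. Genes with a mean of at least 0.5 FPKM over the 12 libraries were tested, 15526 in number. The model left 6 residual degrees of freedom, with 3.06 prior degrees of freedom. P-values were adjusted by the Benjamini-Hochberg method within each of 6 comparisons, and an adjusted p under 0.05 counted as passing. The comparisons were KO minus WT in T, KO minus WT in N, T minus N in WT, T minus N in KO, the genotype by tissue interaction, and 4 minus 3 months. The 5-month libraries were not compared with the other ages, since they stand in their own table. Fold changes are log2 differences of FPKM + 1, which understates changes of genes with low FPKM. Differences at 1 age, between 1 library and 1 library, carry no p-value: a gene was counted when it differed by at least 1 log2 unit and reached 5 FPKM in the higher library. Genes apart by at least 1 log2 unit with the same sign at all 3 ages were also counted, and compared with the counts after swapping the genotypes at 1 age.

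A total of 29 gene lists were written from general knowledge of marker genes, of which 28 held enough tested genes for a list test. They covered MDSC markers, myeloid chemokines and growth factors, cytotoxic T and NK cells, regulatory T cells and checkpoints, macrophages, B and plasma cells, mast cells, the IL-17 axis, Wnt targets, proliferation, colonocyte differentiation, goblet cells, enteroendocrine cells, antimicrobial epithelium and Paneth cells, regenerative and fetal-like epithelium, smooth muscle, fibroblasts and matrix, endothelium, enteric neurons and glia, adipocytes, erythroid cells, the interferon response, MHC class II, the CRL4 ligase, p53 targets, immediate early and heat shock genes, mitochondrially encoded mRNAs, small intestinal enterocytes and sex genes. Lists with at least 3 tested genes were compared with all other genes by camera in limma with a preset correlation of 0.01 between genes, adjusted over the 28 lists tested. The same test with a correlation estimated from the data was run beside it, as was fry, which asks whether the genes of a list move one way on balance and compares them with no other genes. For the list medians at 1 age, percentiles were taken among 10000 random lists matched on expression in 20 bins.

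Genes were named by a rule. It took Cul4b, the 10 genes with the largest change in each direction among those that passed with the same sign at all ages and a mean of at least 2 FPKM in the higher group, and the 3 members of each list with the smallest p. Where fewer than 10 passed in a direction, it was filled with the genes of smallest unadjusted p, to at most 5. Predicted genes with numbered Gm symbols, Rik symbols and immunoglobulin or T cell receptor segments were not named singly. Not every gene that the rule names is reported here. Of the symbols, 103 occurred more than once, so genes were matched by Ensembl ID. The groups, comparisons, lists, naming rule and, except where stated, the alternatives given next were fixed before the data were examined.

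The alternatives tried were a pseudocount of 0.1, no filter, a filter at a mean of 5 FPKM, FPKM rescaled to equal sums per library (TPM) with and without mitochondrial and 430 immunoglobulin genes, median-of-ratios scaling over all 12 libraries, no age term, an age term within each tissue, T and N of an age and genotype treated as 1 animal, a model of only the 2 groups compared, the table of 3 and 4 months alone, and leaving out each library and each age. In the model with an age term within each tissue, T minus N is the fitted difference at 3 months and not a mean over the ages. KO minus WT and the interaction stay over all 3 ages there. Rescaled values were filtered on the deposited FPKM, a choice made after the data were seen. Limma voom on the recovered reads, with the deposited scaling or scaled by their sums, and for the lists leaving out the KO N library of 3 months and the age term within tissue, were chosen after seeing the data.

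The pairing of libraries by age was checked on each library's deviation from the mean of its group. WT and KO libraries of the same tissue and age correlated at 0.666 to 0.781 in T and 0.340 to 0.632 in N, each more than with any other age. T and N libraries of the same age correlated at -0.026 to 0.043 at 4 months, and so did not pair there. Across genes, libraries of the same tissue and age but other genotype correlated at 0.972 to 0.985, and those of a group at other ages at 0.904 to 0.973. The ratio of read variance to Poisson variance ranged from 101 to 333 over pairs of libraries of a group. Between groups the closest pairs were WT T and KO T of 4 months (25.1) and of 3 months (35.2), still far above the ratio of 1 that counting error alone would give.

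The model was tested on simulated data with 100 genes changed 2-fold and 100 changed 4-fold. It recovered 47% and 84% of them for KO minus WT in T, 38% and 85% in N, 39% and 81% for T minus N in WT, 9% and 60% for the interaction, and 64% and 90% for 4 minus 3 months. The list test recovered the 1 list planted and called 0 of 20 others, all in simulated data. In the real lists the estimated correlation between genes ran from -0.058 (CRL4 ligase) to 0.93 (smooth muscle), against the preset 0.01. The simulation is therefore no measure of how often the preset correlation gives false calls in the real lists. Python 3.11.15 with pandas 2.3.3, numpy 2.4.6 and matplotlib 3.10.9 prepared the tables and plots.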

Results

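RNA sequencing profiled the colon of ApcMin/+ mice, which carry a truncating mutation of the tumor suppressor Apc and develop intestinal adenomas. Mice were wild type for Cul4b (WT) or had Cul4b deleted in the intestinal epithelium (KO). Cul4b encodes a scaffold of CRL4 ubiquitin ligases. Adenoma (T) and adjacent normal colon (N) were each represented by 1 library per genotype at 3, 4 and 5 months, which gave 12 libraries in 4 groups of 3. Reads assigned to genes ranged from 18263611 to 25321931 per library, with a median of 21183824. Since the labels do not say that the libraries came from separate animals, all p-values measure only the spread between these libraries.

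Cul4b (ENSMUSG00000031095, mm10 chromosome X, 38533274 to 38576196) was the targeted gene. In N, its level was 13.4 ± 1.75 FPKM in WT and 1.76 ± 1.08 FPKM in KO (SD, n = 3). In T, it was 10.02 ± 2.18 FPKM in WT and 1.76 ± 0.446 FPKM in KO (SD, n = 3). The deposited tables of 3 to 4 months and of 5 months were normalized separately, so these means join 2 scales, while each difference between genotypes lies within a table. Cul4b fell by 1.99 on the log2 scale in KO T (SE 0.18, limma adjusted p = 0.021) and was lower at all 3 ages. In KO N, Cul4b fell by 2.45 on the log2 scale (SE 0.18, limma adjusted p = 0.0036), also at all 3 ages. Over 27 alternative settings the difference stayed between -2.58 and -1.93 in T, and it passed in 11 of them (limma adjusted p 0.0076 to 1). Leaving out any T library, the WT N library of 5 months, the KO N library of 4 months or any age ended the call in T, with limma adjusted p of 0.15 to 0.26 without a T library, 0.0897 without that WT library, 0.0664 without that KO library and 0.346 to 1 without an age. In N, Cul4b passed in 22 of 27 settings (limma adjusted p 0.0025 to 0.949), and leaving out the KO library of 4 months (0.0542) or any age (0.0544 to 0.949) ended the call. A difference in residual Cul4b between KO T and KO N did not pass (log2 difference 0.05, SE 0.18, limma adjusted p = 0.85).

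**Figure D1:**
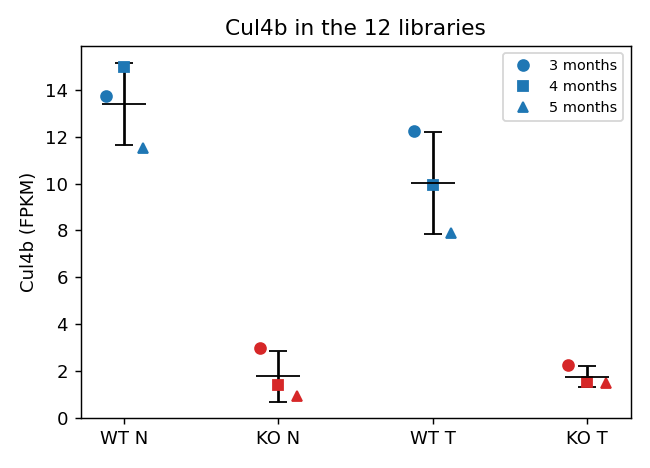
Cul4b expression (FPKM, vertical axis) in each of the 12 libraries by genotype and tissue, with age as the marker shape and the mean and SD of 3 libraries in black; ages 3 and 4 months and age 5 months come from tables normalized separately. KO libraries lie between 0.920 and 2.98 FPKM and WT libraries between 7.88 and 14.96 FPKM.

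Adenoma was compared with adjacent normal colon in each genotype to describe the tumors that form with and without epithelial Cul4b. Inhibitors and targets of Wnt signaling, the pathway that loss of Apc activates, were among the genes with the largest rise. In WT, Notum (ENSMUSG00000042988, chromosome 11, 120653788 to 120661175), a secreted Wnt inhibitor, rose by 4.21 on the log2 scale (SE 0.53, limma adjusted p = 0.00048), from 2.25 ± 2.42 to 50.9 ± 15.5 FPKM (SD, n = 3). The Wnt feedback gene Nkd1 (ENSMUSG00000031661, chromosome 8, 88521354 to 88594884) rose by 4.32 (SE 0.54, limma adjusted p = 0.00048). Wif1 (ENSMUSG00000020218, chromosome 10, 121033960 to 121100650), another secreted Wnt inhibitor, rose by 4.18 in WT (SE 0.66, limma adjusted p = 0.0014) and rose by 4.96 in KO (SE 0.66, limma adjusted p = 0.00075). Of 22 Wnt targets tested, 21 rose in each genotype, with median differences of 2.15 in WT and 2.16 in KO, and 21 rose in each when adjusted over the list alone. Sp5 rose by 2.61 in WT and 2.75 in KO, and Rnf43 by 2.36 and 2.47. Against all other genes the Wnt list passed in WT (camera adjusted p = 4.6e-12) and in KO (4.8e-14), but not with an estimated correlation (adjusted p = 0.23 and 0.24 with an estimated correlation).

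Genes of mature colonocytes and goblet cells were the counterpart. Fabp2 (ENSMUSG00000023057, chromosome 3, 122895072 to 122899506), which encodes a fatty acid binding protein of absorptive cells, was 1478 ± 391 FPKM in WT N and 2.06 ± 0.73 FPKM in WT T (SD, n = 3). It fell by 8.91 on the log2 scale in WT (SE 0.68, limma adjusted p = 5.4e-05) and fell by 6.94 in KO (SE 0.68, limma adjusted p = 0.00017). Of 18 colonocyte genes tested, 15 fell in WT and 16 in KO, and 16 fell in each when adjusted over the list alone; the medians were -4.20 and -4.22. The transporter gene Slc51b fell by 6.09 in WT and fell by 5.54 in KO, and Slc16a1 fell by 2.52 and fell by 2.09. All 12 goblet cell genes fell in both genotypes, over all genes and adjusted over the list alone, with medians of -3.25 and -3.68. The mucin gene Muc2 fell by 5.14 in WT and fell by 4.80 in KO, and Spdef, a goblet cell transcription factor, fell by 3.33 and fell by 3.65. Of 10 enteroendocrine genes, 7 fell and 1 rose in each genotype, or 8 and 1 adjusted over the list alone, and Gcg fell by 4.22 and fell by 3.68. The list tests passed for colonocytes (camera adjusted p = 7.8e-09 in WT and 4.9e-10 in KO), goblet cells (7.0e-08 and 4.9e-09) and enteroendocrine cells (0.00059 and 0.00036). None passed with an estimated correlation (adjusted p = 0.20 in WT and 0.15 in KO with an estimated correlation, for each list).

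Markers of myeloid-derived suppressor cells (MDSC), which are immature myeloid cells that restrain T cells, rose in the adenomas of both genotypes. Of 19 MDSC markers, 15 rose in WT, with a median difference of 2.26, and 12 rose and 1 fell in KO, with a median of 1.93; adjusted over the list alone, 15 rose in WT, and 13 rose and 1 fell in KO. S100a8, which encodes a neutrophil calcium-binding protein, rose by 3.88 in WT and 4.29 in KO. Il1b rose by 3.75 and 3.56, and Arg1, which encodes an arginase that depletes arginine from T cells, by 3.36 and 3.79. Of 20 myeloid chemokines and growth factors, 14 rose and 1 fell in WT and 13 rose in KO, or 14 and 2, and 13 and 2, adjusted over the list alone. The neutrophil chemokine gene Cxcl5 rose by 4.13 in WT and 4.75 in KO. The camera adjusted p was 1.1e-07 and 1.2e-06 for MDSC markers and 4.3e-05 and 0.00034 for chemokines. Neither list passed with an estimated correlation (adjusted p = 0.23 and 0.29, and 0.23 and 0.24, with an estimated correlation).

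**Figure D2:**
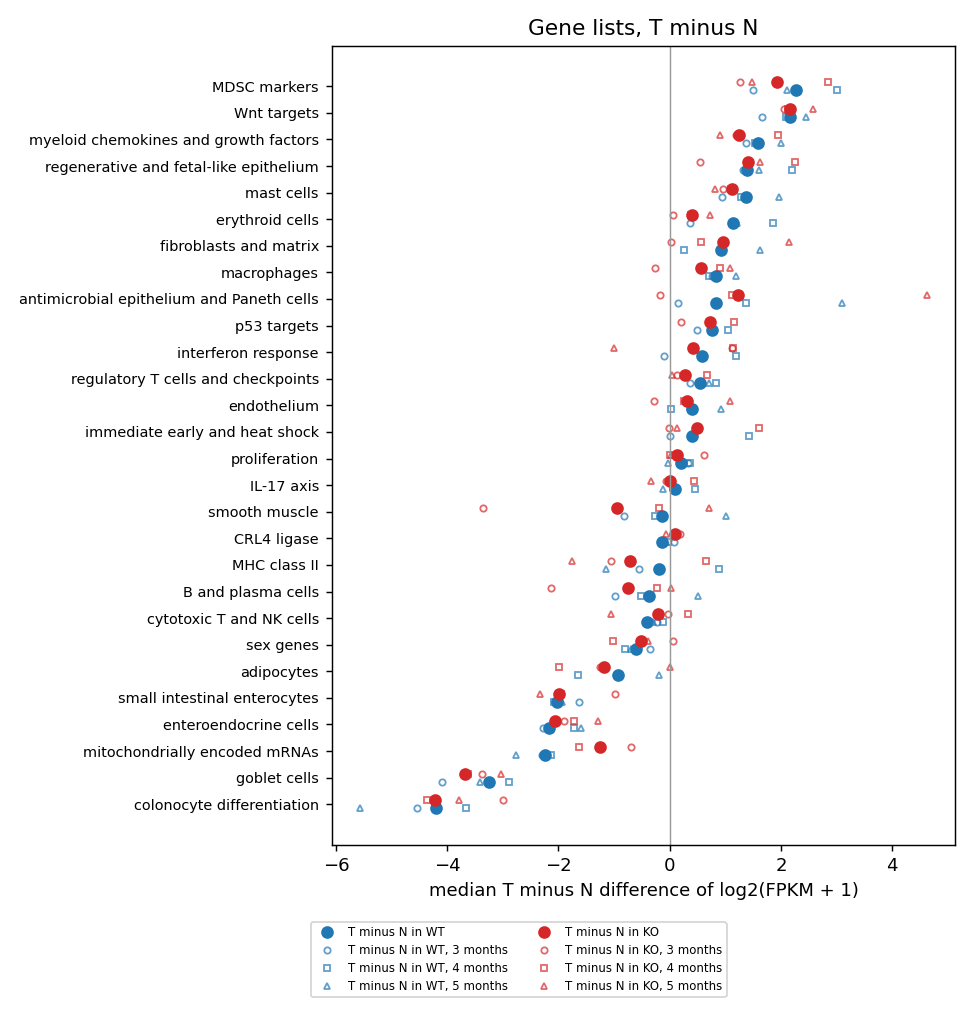
Median T minus N difference of log2(FPKM + 1) (horizontal axis) of each gene list (vertical axis), in WT in blue and KO in red; large points are the fitted medians and small open points the 3 ages. Wnt targets (2.15 and 2.16), MDSC markers (2.26 and 1.93), goblet cells (-3.25 and -3.68) and colonocytes (-4.20 and -4.22) lie far from 0 in both genotypes.

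Another 8 lists passed in 1 or both genotypes, of which mitochondrially encoded mRNAs are given below. Small intestinal enterocyte genes fell (5 of 8 in each genotype; medians -2.03 and -1.99; camera adjusted p = 0.0087 and 0.0030; adjusted p = 0.36 and 0.29 with an estimated correlation), with the apolipoprotein gene Apob at -2.51 in WT and -2.30 in KO. In the mast cell list 3 of 7 genes rose in WT and 2 in KO, including Hdc, the histamine-forming enzyme gene, by 2.26 and 1.92 (camera adjusted p = 0.0083 and 0.00996; adjusted p = 0.23 and 0.24 with an estimated correlation). Among p53 targets 5 of 13 rose and 1 fell in WT and 4 rose in KO, with Phlda3 up by 2.66 and 2.70 (camera adjusted p = 0.0083 and 0.0025; adjusted p = 0.54 and 0.42 with an estimated correlation). In the regenerative and fetal-like list 6 of 11 genes rose in WT and 5 in KO, with the keratin gene Krt7 up by 1.793 and 2.001 (camera adjusted p = 0.034 and 0.00996; adjusted p = 0.54 and 0.49 with an estimated correlation). Fibroblast and matrix genes rose in 5 of 14 in each genotype, with the fibronectin gene Fn1 up by 3.09 and 2.90 (camera adjusted p = 0.0087 and 0.0086; adjusted p = 0.64 and 0.71 with an estimated correlation). Among macrophage genes 6 of 13 rose in WT and 4 in KO, with Msr1, a scavenger receptor gene, up by 1.13 and 1.05 (camera adjusted p = 0.0043 and 0.048; adjusted p = 0.54 and 0.71 with an estimated correlation). In the regulatory T cell and checkpoint list 4 of 10 genes rose in WT and 1 in KO, and the list passed in WT alone (camera adjusted p = 0.031 in WT and 0.22 in KO; adjusted p = 0.54 and 0.71 with an estimated correlation); its checkpoint gene Havcr2 rose by 0.82 and 0.63. Adjusted over the list alone, genes passing in WT and KO were 5 and 5 for enterocytes, 6 and 3 for mast cells, 10 (9 up) and 8 for p53 targets, 6 and 6 for regenerative genes, 5 and 5 for fibroblasts, 6 and 4 for macrophages and 4 and 0 for regulatory T cells. Without the libraries of 4 months, 3 calls in WT ended, for enterocytes (camera adjusted p = 0.067), regenerative genes (0.25) and regulatory T cells (0.051). In KO, leaving out 4 months ended those for macrophages (0.18) and regenerative genes (0.061), and leaving out 5 months ended those for macrophages (0.26) and fibroblasts (0.18). With the age term within each tissue, T minus N is the fitted difference at 3 months, another quantity than the difference over all ages. At 3 months the WT lists of enterocytes (0.078), p53 targets (0.14), fibroblasts (0.18), macrophages (0.23), regulatory T cells (0.17) and regenerative genes (0.24) did not pass. Neither did the KO lists of p53 targets (0.091), fibroblasts (0.18), macrophages (0.86) and regenerative genes (0.10). The KO macrophage median was -0.27 at 3 months, against 0.90 and 1.09 at 4 and 5 months. The WT call for p53 targets ended with the filter at a mean of 5 FPKM (0.069), and the KO call for macrophages without the age term (0.075). Over the alternatives, the 3-month fit included, the camera adjusted p of the lists that ended or did not pass ranged from 0.00012 to 0.86.

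Apart from mitochondrially encoded mRNAs, the remaining lists did not pass in either genotype. Their medians in WT and KO were -0.41 and -0.22 for cytotoxic T and NK cells, -0.38 and -0.75 for B and plasma cells, 0.09 and 0.01 for the IL-17 axis, 0.21 and 0.14 for proliferation, and 0.82 and 1.23 for antimicrobial epithelium and Paneth cells. They were -0.15 and -0.95 for smooth muscle, 0.40 and 0.32 for endothelium, -0.94 and -1.17 for adipocytes, 1.13 and 0.40 for erythroid cells, 0.58 and 0.42 for the interferon response, and -0.19 and -0.71 for MHC class II. They were -0.15 and 0.10 for the CRL4 ligase, 0.40 and 0.49 for immediate early and heat shock genes, and -0.60 and -0.51 for sex genes. Of the enteric neuron and glia list 2 genes were tested, too few for a list test, and their median was 0.35 and 0.24. The age term within each tissue makes T minus N the fitted difference at 3 months. In that fit smooth muscle passed as lower in T (camera adjusted p = 0.0027 in WT and 1.7e-05 in KO). So did B and plasma cells (0.027 and 0.00069) and, in KO, MHC class II (0.026). These are results of 3 months alone: smooth muscle medians in WT and KO were -0.82 and -3.365 at 3 months but 1.02 and 0.71 at 5 months. Over the alternatives the camera adjusted p of these lists ranged from 1.7e-05 to 0.96. Other lists passed in some alternatives: immediate early and heat shock genes in 3 of 9 in each genotype, and the interferon response in 2 of 9 in each. Adipocytes passed in 1 of 8 in each, sex genes in 1 of 8 in WT and 2 of 8 in KO. Erythroid cells passed in 1 of 9 in WT and endothelium in 2 of 8 in KO. In these cases the camera adjusted p ranged from 6.1e-05 to 0.89 over the alternatives. Single members passed all the same. Among cytotoxic genes 3 of 11 fell in WT and 0 in KO by limma (the same counts adjusted over the list alone), and the granzyme gene Gzma fell by 2.18 in WT (limma adjusted p = 0.0031) and had a difference of -1.11 in KO (limma adjusted p = 0.066). The antimicrobial genes Lcn2, which encodes an iron-binding protein of inflamed epithelium, and Pigr, the receptor that exports IgA, parted: Lcn2 rose by 3.92 and 4.17 and Pigr fell by 2.73 and fell by 2.79. Cxcl10, a chemokine gene induced by interferon, rose by 3.02 and 2.99.

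In all, 2526 genes rose and 3086 fell in WT T against N, and 2168 rose and 2483 fell in KO (limma); 1239 and 1719 of the WT genes and 1112 and 1396 of the KO genes changed at least 2-fold. Voom called 5875 genes in WT, 5456 of them shared, and 4893 in KO, 4501 of them shared. In both genotypes 1939 genes rose, where 353 would be shared by chance, and 2295 fell, where 494 would be; 0 genes passed in opposite directions. Across the 15526 genes, which are not independent replicates, the differences in KO and WT correlated at 0.948 (Pearson) and 0.914 (Spearman). Genes with the largest rise that share reads with close relatives, and whose assignment is therefore uncertain, were Lyz1 (4.64 in WT and 5.53 in KO) and the Paneth cell defensin gene Defa22 (4.48 and 5.30). Others with large rises were Spock2 (4.72 and 5.28), a proteoglycan gene, the metallothionein gene Mt4 (4.49 and 5.45), and, in KO, the matrix metalloproteinase gene Mmp10 (5.02). Falls beyond 6 log2 units in WT also included Retnlb (-8.08), a goblet cell gene, Cyp2c65 (-7.85), Tmigd1 (-7.50), Reg3b (-7.17), Apol10a (-6.95) and Car1 (-6.76), a colonocyte carbonic anhydrase gene. Leaving out the 5-month libraries lowered the counts to 2461 in WT and 1997 in KO, and leaving out those of 4 months lowered the count in KO to 2950.

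Mitochondrially encoded mRNAs took 9.04 ± 1.90% of reads in the 6 N libraries and 3.72 ± 1.24% in the 6 T libraries (SD). All 13 fell in WT T, with a median of -2.25, and 7 fell in KO T, with a median of -1.25; adjusted over the list alone, 13 and 10 fell. Reads of these genes can also come from nuclear copies, so their levels are uncertain. The list passed in both genotypes (camera adjusted p = 9.1e-08 and 0.00023), though not with an estimated correlation (adjusted p = 0.25 and 0.42 with an estimated correlation). The share of rising genes depended on the scaling between tissues. The 10 most abundant genes took 13.7 ± 1.33% of reads in N and 6.35 ± 0.897% in T (SD, n = 6). As deposited, 45.01% of the genes called in WT and 46.6% in KO rose. After rescaling to equal sums per library (TPM) these shares were 87.5% and 84.4%, and the median of all genes shifted by 0.76 in WT and 0.57 in KO; without mitochondrial and immunoglobulin genes they were 84.7% and 82.5%, with shifts of 0.67 and 0.53. Relative to that shift under TPM, Wnt targets stood at 2.40 and 2.45, MDSC markers at 2.56 and 2.30, colonocyte genes at -4.81 and -4.57 and goblet cell genes at -3.27 and -3.72. The Y-linked genes Ddx3y, Uty and Eif2s3y fell by 0.61, fell by 0.59 and fell by 0.76 in WT T as deposited, but lay above 0 after TPM rescaling (0.23, 0.14 and 0.10).

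KO and WT adenomas were compared to ask how epithelial Cul4b loss alters the tumors, including the mRNA of MDSC markers. Some of these markers are also genes of neutrophils and monocytes, so their levels do not count MDSC. Apart from Cul4b, 0 of the 15526 genes changed in T by limma; 128 had an unadjusted p under 0.05, where 776 would by chance, and voom called 1 gene with 129 under 0.05. With the age term within each tissue 412 genes had an unadjusted p under 0.05 and 0 passed, Cul4b included. In the model of only the 2 groups these were 707 and 0. The age term of the main model is shared by T and N, so age differences particular to a tissue enter its spread. Its low count is therefore no evidence that Cul4b loss left the other genes unchanged. MDSC markers were not higher in KO: 14 of 19 lay below 0, with a median difference of -0.26, and the medians at 3, 4 and 5 months were -0.05, -0.19 and -0.38. Among them Trem1, a receptor gene of neutrophils and monocytes, differed by -0.56, Ptgs2 by -0.55 and Il1b by -0.49, and 0 of the 19 passed by limma over all genes or adjusted over the list alone. Against other genes the MDSC list was lower in KO T (camera adjusted p = 0.00056), but not with an estimated correlation (adjusted p = 0.61 with an estimated correlation). Without the 5-month libraries its camera adjusted p was 0.078, in a range of 1.3e-05 to 0.078 over 9 alternatives. Myeloid chemokines had a median of -0.15 (camera adjusted p = 0.014; adjusted p = 0.54 with an estimated correlation), and without the 5-month libraries the test gave the opposite direction (camera adjusted p = 0.72; range over 9 alternatives 3.1e-05 to 0.72). The chemokine call also ended with the age term within each tissue (0.083) and with the filter at a mean of 5 FPKM (0.10). The monocyte chemokine genes Ccl3 (-1.43, SE 0.39) and Ccl4 (-1.03, SE 0.31) lay lower in KO and did not pass (limma adjusted p = 1).

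Further lists separated KO from WT adenomas by the preset correlation alone. Proliferation genes lay below 0 in 20 of 22, with a median of -0.17 (camera adjusted p = 2.4e-06; adjusted p = 0.41 with an estimated correlation) and 0.10, -0.29 and -0.27 at 3, 4 and 5 months. Erythroid genes, whose globin members share reads, had a median of -1.34 in T (camera adjusted p = 8.1e-09, and 0.34 with an estimated correlation). It was 0.55, -2.76 and -1.83 at 3, 4 and 5 months. The fall was not particular to T, since all 5 erythroid genes also lay below 0 in N (median -0.61, camera adjusted p = 0.051). Mitochondrially encoded mRNAs lay above 0 in all 13, with a median of 0.46 (camera adjusted p = 2.7e-13; adjusted p = 0.34 with an estimated correlation) and 0.64, 0.28 and 0.60 at 3, 4 and 5 months, and 1 of them passed adjusted over the list alone. These 3 lists passed in all 9 alternatives (camera adjusted p up to 0.047). Immediate early and heat shock genes had a median of -0.18 (camera adjusted p = 0.0055; adjusted p = 0.71 with an estimated correlation) and mast cell genes of -0.22 (camera adjusted p = 0.047; adjusted p = 0.53 with an estimated correlation). Without the 5-month libraries these were 0.13 and 0.62, and the mast cell list also failed without the 3-month libraries (0.19) or the KO N library of 3 months (0.090). It failed with a pseudocount of 0.1 (0.055) and without the age term (0.063) as well. The ranges of the 2 lists over the alternatives were 0.00021 to 0.13 and 3.1e-05 to 0.62. The other 21 lists did not pass, among them cytotoxic T and NK cells (median 0.05; camera adjusted p = 0.16, but 1.9e-06 and higher in KO without the 5-month libraries, in a range of 1.9e-06 to 0.48 over 9 alternatives), regulatory T cells and checkpoints (-0.09) and Wnt targets (-0.05). Leaving out an age changed this for other lists too. The interferon response passed as higher in KO without the 5-month libraries (camera adjusted p = 1.5e-08) and as lower without those of 3 months (0.00098) or 4 months (0.027). Its range over 9 alternatives was 1.5e-08 to 0.54. Colonocyte genes passed as higher without the 4-month libraries (3.1e-05, in a range of 3.1e-05 to 0.87). Regulatory T cells passed as lower without those of 3 months (0.0062) or 4 months (0.046), in a range of 0.0062 to 0.53. Without the 3-month libraries goblet cell (0.0026) and CRL4 ligase (0.038) genes passed as lower and p53 targets (0.015) as higher. Without those of 5 months macrophage (0.024) and B and plasma cell (0.045) genes passed as higher. Over the alternatives these 5 lists ranged from 0.0026 to 0.99. Without the KO N library of 3 months colonocyte genes passed as higher (0.018) and smooth muscle as lower (0.016, in a range of 0.016 to 0.33). Smooth muscle also passed with the age term within each tissue (0.047). Without the age term colonocyte genes (0.030), regulatory T cells (0.034), the IL-17 axis (0.034, in a range of 0.034 to 0.28) and the CRL4 ligase (0.042) passed. Medians and means differed in sign for B and plasma cells, enteroendocrine cells, antimicrobial epithelium and fibroblasts. The genes with the smallest unadjusted p other than Cul4b included Slc15a2 (1.12), Crip1 (0.72) and Cd302 (0.55), which lay higher in KO, and the heparin-binding growth factor gene Mdk (-0.74), which lay lower; none passed (limma adjusted p = 1).

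**Figure D3:**
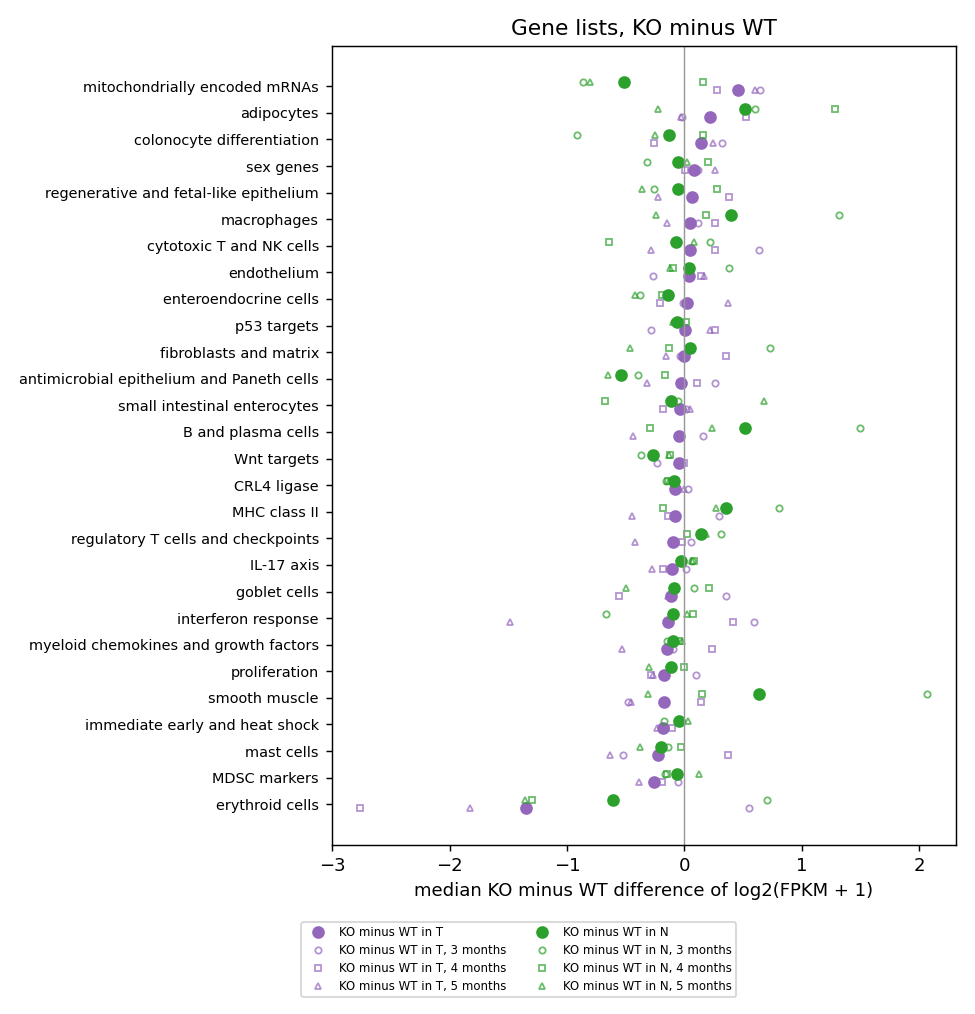
Median KO minus WT difference of log2(FPKM + 1) (horizontal axis) of each gene list (vertical axis), in T in purple and N in green; large points are the fitted medians and small open points the 3 ages. MDSC markers lie at -0.26 in T and -0.06 in N, and smooth muscle in N ranges from -0.31 at 5 months to 2.07 at 3 months.

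The same comparison in adjacent normal colon asked what Cul4b loss changes outside the adenomas. Apart from Cul4b, 0 genes changed in N by limma; 228 had an unadjusted p under 0.05, and voom called 1 gene with 142 under 0.05. With the age term within each tissue 683 genes had an unadjusted p under 0.05, without the WT N library of 4 months 602 and without the KO N library of 4 months 647. In these fits 1, 1 and 0 genes passed, Cul4b included. As in T, the low count of the main model is no evidence that the other genes were unchanged. All 22 Wnt targets lay below 0 in KO N, with a median of -0.26 (camera adjusted p = 0.0012, and 0.70 with an estimated correlation). The medians were -0.37, -0.13 and -0.13 at 3, 4 and 5 months, at percentiles 0, 1.69 and 49.3 of matched random lists. Notum was 5.03 FPKM at 3 months and 1.14 FPKM at 4 months in WT N, against 1.59 and 1.08 FPKM in KO N. Of genes outside the list that rose in T, Spock2 was 6.11 and 1.38 FPKM in WT N, against 2.05 and 1.68 FPKM in KO N. Mt4 was 63.2 and 13.4 FPKM against 17.1 and 24.3 FPKM. The mean log2(FPKM + 1) of the Wnt list was 2.554 and 2.095 in WT N, against 2.045 and 1.941 in KO N. The fall at 3 months thus cannot be told apart from a trait of the WT library of 3 months. Whether that library makes the call of this list was not tested. Without the 3-month libraries the camera adjusted p of the Wnt list was 0.076, and without those of 4 months 0.095. Its range over 9 alternatives was 2.2e-06 to 0.095. Smooth muscle genes lay above 0 in all 12 (median 0.64, camera adjusted p = 4.1e-05), as did B and plasma cell genes in all 14 (0.52, 3.9e-06) and macrophage genes in 12 of 13 (0.40, 4.3e-07); these calls too were lost (adjusted p = 0.63, 0.63 and 0.51 with an estimated correlation). They rested on the KO library of 3 months: medians at 3, 4 and 5 months were 2.07, 0.15 and -0.31 for smooth muscle, 1.495, -0.29 and 0.23 for B and plasma cells, and 1.32, 0.18 and -0.24 for macrophages. Without that library only Wnt targets of the 10 lists remained (camera adjusted p = 0.00058), while fibroblast and erythroid genes passed as lower in KO (0.019 and 0.00058). That fit still held the WT N library of 3 months. With all libraries the fibroblast medians were 0.73, -0.13 and -0.46 at 3, 4 and 5 months, and the erythroid medians 0.71, -1.30 and -1.36. Over 9 alternatives these 2 lists ranged from 5.9e-05 to 0.52 and from 6.1e-12 to 0.70. Without the KO library of 3 months smooth muscle stood at 0.16, B and plasma cells at 0.45 and macrophages at 0.99. Their ranges over 9 alternatives were 4.2e-09 to 0.82, 4.2e-09 to 0.93 and 1.9e-13 to 0.99. Mitochondrially encoded mRNAs had a median of -0.51 (camera adjusted p = 3.3e-09; adjusted p = 0.51 with an estimated correlation) and of -0.87, 0.16 and -0.80 at 3, 4 and 5 months, with 1 of 13 passing adjusted over the list alone, and a camera adjusted p of 0.061 without that library (range over 9 alternatives 4.7e-11 to 0.061).

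Of the other lists that passed in N, MHC class II had a median of 0.35 (camera adjusted p = 0.015; adjusted p = 0.70 with an estimated correlation), regulatory T cells and checkpoints of 0.15 (0.017; adjusted p = 0.63 with an estimated correlation) and adipocytes of 0.52 (0.024; adjusted p = 0.51 with an estimated correlation). Enteroendocrine genes had a median of -0.14 (camera adjusted p = 0.027; adjusted p = 0.51 with an estimated correlation), and 1 of 10 passed adjusted over the list alone. The CRL4 ligase list, which holds Cul4b, had a median of -0.09 (camera adjusted p = 0.0086; adjusted p = 0.46 with an estimated correlation). Without the KO library of 3 months these stood at camera adjusted p = 0.45, 0.82, 0.085, 0.16 and 0.16, in ranges over the alternatives of 0.00056 to 0.57, 0.0014 to 0.82, 0.00013 to 0.46, 0.0073 to 0.31 and 0.0013 to 0.16. Leaving out the 4-month libraries also ended the calls for adipocytes (0.46), enteroendocrine genes (0.21) and the CRL4 ligase (0.095), and leaving out those of 5 months the call for regulatory T cells (0.064). The call for enteroendocrine genes also ended with the age term within each tissue (0.071) and without the age term (0.074). It ended with a pseudocount of 0.1 (0.11) and with the filter at a mean of 5 FPKM (0.31) as well. That pseudocount ended the call for adipocytes too (0.21). Leaving out the 3-month libraries ended those for MHC class II (0.57), regulatory T cells (0.63), adipocytes (0.079) and the CRL4 ligase (0.076). Antimicrobial epithelium and Paneth cell genes lay below 0 in 12 of 14, with a median of -0.54 and -0.39, -0.16 and -0.65 at 3, 4 and 5 months. The list did not pass (camera adjusted p = 0.051) but did in 5 of 9 alternatives (range 0.0081 to 0.17, the lowest with the age term within each tissue). Its defensin and lysozyme members share reads. MDSC markers (median -0.06) and myeloid chemokines (-0.09) did not pass in N. Medians and means differed in sign for the IL-17 axis and small intestinal enterocytes. Fabp6, an ileal bile acid binding protein gene, had means of 19.2 FPKM in WT and 71.9 FPKM in KO and a log2 difference of 2.08, and the metallothionein gene Mt1 one of 1.87; both lay higher at all 3 ages and neither passed (limma adjusted p = 1). Cck, a gut hormone gene, differed by -0.68 and did not pass either.

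The interaction asked whether the effect of Cul4b loss differed between adenoma and normal colon. For 0 genes did it differ by limma (smallest adjusted p = 0.9996). An unadjusted p under 0.05 was found for 183 genes, and for 605 with the age term within each tissue. Voom called 0 with 129 under 0.05. These counts are no evidence that the effect was alike in T and N. The difference for Cul4b itself was 0.45 (SE 0.25, limma adjusted p = 0.9996). Mitochondrially encoded mRNAs had a median interaction of 0.99 (camera adjusted p = 1.5e-18; adjusted p = 0.35 with an estimated correlation); 7 of 13 passed adjusted over the list alone, and the list passed in all 9 alternatives (up to 1.1e-07). At 4 months its interaction median was 0.0758, against 1.42 at 3 months and 1.38 at 5 months. Another 9 lists passed with negative medians: smooth muscle (-0.92), erythroid cells (-0.73), B and plasma cells (-0.53), MHC class II (-0.45), macrophages (-0.34), regulatory T cells (-0.23), MDSC markers (-0.23), myeloid chemokines (-0.20) and the IL-17 axis (-0.07). None of these 9 kept its call (adjusted p = 0.66 with an estimated correlation), and none passed without the KO N library of 3 months (camera adjusted p 0.22 to 0.99). Their camera adjusted p over the alternatives ranged from 3.1e-08 to 0.99. Without the 3-month libraries the calls for macrophages (0.82), B and plasma cells (0.36), smooth muscle (0.30) and MHC class II (0.17) ended, and without those of 4 months the calls for erythroid cells (0.31) and the IL-17 axis (0.073). Without those of 5 months the calls for MDSC markers (0.53), myeloid chemokines (0.94), regulatory T cells (0.37), MHC class II (0.12) and the IL-17 axis (0.12) ended. The age term within each tissue ended the calls for myeloid chemokines (0.061), the IL-17 axis (0.063) and erythroid cells (0.083), and the filter at a mean of 5 FPKM that for MDSC markers (0.12). A model without the age term ended those for myeloid chemokines (0.064), erythroid cells (0.086) and MHC class II (0.061). A pseudocount of 0.1 ended those for myeloid chemokines (0.087) and the IL-17 axis (0.070). TPM rescaling shifted the median of all genes by -0.18 here, and relative to that shift the mitochondrial list stood at 0.92, smooth muscle at -1.02 and MDSC markers at -0.22.

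Comparing single libraries of the same age and tissue, without replicates, 133 genes were higher and 57 lower in KO T at 3 months, 61 and 68 at 4 months, and 188 and 143 at 5 months. In N these counts were 285 and 171, 71 and 55, and 205 and 186. Retnlb, a goblet cell gene, was higher in KO T at 3 months (2.46) and 5 months (4.98) and lower at 4 months (-3.44). At 5 months the interferon-induced genes Oas2 (-2.59) and Isg15 (-2.45) were lower in KO T. The median of the interferon list was -1.48 there but 0.59 and 0.42 at 3 and 4 months, at percentiles 0, 100 and 100 of random lists. The posterior homeobox genes Hoxd12 (4.35) and Hoxd13 (2.90) were higher in KO T at 5 months, while Hoxd12 at 4 months was 1.96 FPKM in KO and 10.4 FPKM in WT. In N at 3 months the smooth muscle genes Synm (2.68) and Actg2 (2.65) were higher in KO and the colonocyte genes Cyp2c65 (-3.93) and Car1 (-3.68) lower. Cyp2c55 in N was higher in KO at 5 months (3.29), but 27.2 FPKM in KO against 285 FPKM in WT at 3 months and 904 against 880 FPKM at 4 months. The Paneth and goblet cell antimicrobial gene Ang4 in N was lower in KO at 5 months (-6.45), but 7742 FPKM in KO against 4722 FPKM in WT at 3 months. At 3, 4 and 5 months the MDSC median of T lay at percentiles 20.6, 0.060 and 0 of random lists matched on expression, and that of N at 9.65, 1.22 and 98.8. At all 3 ages, 5 genes in T were at least 2-fold apart the same way, Cul4b among them, where swapping the genotypes at 1 age gave 5 or 6; in N these were 10, with Cul4b, Fabp6, Mt1 and Mir145a among them, where swaps gave 4 to 9.

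Age was compared within the table of 3 and 4 months. From 3 to 4 months 2 genes rose and 3 fell (limma), with 3162 at an unadjusted p under 0.05; voom called 1 gene, with 3895 under 0.05. Hoxa11os, a transcript antisense to Hoxa11, fell by 1.80 (SE 0.20, limma adjusted p = 0.037) and was lower at 4 months in all 4 groups. It was 12.5 to 17.1 FPKM at 3 months, 1.92 to 4.86 FPKM at 4 months and, on the separate scale of its table, 13.9 to 15.3 FPKM at 5 months. The low value at 4 months thus cannot be told apart from a trait shared by the libraries of that age. Whether a read came from the strand of Hoxa11os was not resolved, so its level is uncertain. Chosen after their values were seen, the other 4 were the immunoglobulin segments Ighv1-80 (1.97) and Igkv12-98 (2.07), which share reads with related segments, and the predicted RNA genes Gm27817 (-2.42) and Gm27454 (-2.06). At 5 months Gm27817 and Gm27454 also stood high again, at 9.11 to 19.8 and 4.41 to 5.89 FPKM. Leaving out single libraries gave 0 to 4 genes, and 0 to 2 for each library except WT T of 5 months. The homeobox gene Hoxa5 differed by -1.33 (limma adjusted p = 0.065), and Abcc3, a gene of a bile acid exporter, by 0.88 (limma adjusted p = 0.108); neither passed.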

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

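The tests of a mixed sample, of epithelial share, of mitochondrial content and of scaling were chosen after the results were seen, and the mitochondrial and smooth muscle lists were first joined as 1 pattern and parted after a first look; the counts over other splits of the libraries were planned.

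The effect of Cul4b loss on 10 gene lists differed between T and N by the list test of the interaction with a preset correlation. The median of the KO minus WT difference in T minus that in N was -0.23 for MDSC markers, -0.20 for myeloid chemokines and growth factors, -0.23 for regulatory T cells and checkpoints, -0.34 for macrophages and -0.53 for B and plasma cells. It was -0.0727 for the IL-17 axis, -0.92 for smooth muscle, -0.73 for erythroid cells, -0.45 for MHC class II and 0.99 for mitochondrially encoded mRNAs. None passed with an estimated correlation (adjusted p = 0.35 for the mitochondrial list and 0.66 for the others). The genes Atp5l2-ps (0.68), mt-Atp8 (1.86) and Rps15a-ps3 (1.02) lay in opposite directions in T and N at all 3 ages, with that interaction difference on the log2 scale; none passed the test of the difference (limma adjusted p = 0.9996). Atp5l2-ps and Rps15a-ps3 are pseudogenes and mt-Atp8 has nuclear copies, so reads shared with related sequences leave these levels uncertain.

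Smooth muscle, macrophage and B cell lists stood higher in KO N than WT N. The tables argue for a single library: over the 3 lists the medians at 4 and 5 months averaged -0.0464 (-0.08 for smooth muscle, -0.03 for macrophages and -0.03 for B and plasma cells), against 2.07, 1.32 and 1.495 at 3 months. A mixed sample, such as a piece of KO N colon of 3 months that held more muscle and lymphoid tissue, is thus a candidate explanation. A different position of the 3-month N pieces along the colon was not tested and stays open. Of homeobox genes that mark position, the posterior gene Hoxb13 was higher in KO N than WT N (59.29 against 28 FPKM). The more anterior genes Hoxb6 (1.971 against 5.164 FPKM) and Hoxb7 (0.8692 against 5.414 FPKM) were lower. Hoxa5, Hoxa10, Hoxa11 and Hoxa13 ran the other way (Hoxa13 17.81 against 20.99 FPKM). Fewer epithelial cells in all KO N pieces stays open, since over 40 epithelial genes the medians were -0.37, 0.0774 and -0.34 at the 3 ages and the largest, 0.0774, lay within its standard error of 0.10; the rise of other cell types that it needs was not seen at 4 and 5 months, where 70 stromal and immune genes had medians of 0.0067 and -0.16, against 1.17 at 3 months. An effect of genotype at 3 months alone stays open as well, since that age has 1 library per genotype and tissue.

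Mitochondrially encoded mRNAs stood lower in KO N at 3 and 5 months (-0.87 and -0.80) but not at 4 months (0.16), and higher in KO T (0.64, 0.28 and 0.60), so the interaction was 1.42, 0.0758 and 1.38 at the 3 ages. After rescaling to equal sums per library the median interaction difference was 0.74, against 0.99 as deposited. Its standard error over the 3 ages was 0.28, too wide to place it above 0.5 times the deposited value. That width comes from the 4-month value, which was low under both scalings. At 3, 4 and 5 months the rescaled values were 0.99, 0.15 and 0.996, against 1.42, 0.0758 and 1.38 as deposited. They argue against scaling as the whole cause at 3 and 5 months. Scaling as a part of the cause was not excluded. Mitochondrial content stays open in both tissues, by a bound that was changed after the values were seen. At first a difference short of a set share of the mitochondrial median would have excluded it, and it would have been excluded in both tissues. Since that share was an assumption, the bound became a difference of the opposite sign by more than its standard error. In N, 40 nuclear-encoded respiratory chain genes had a median of -0.18, but random lists matched on expression had -0.12, so the difference was -0.0597 (SE 0.0385 over the 3 ages, percentile 3.31). By age it was -0.10, -0.0410 and -0.17 at 3, 4 and 5 months (percentiles 0.51, 24.1 and 0.040). In T their median was 0.0979 against 0.0789 for matched lists, a difference of 0.0190 (SE 0.0481 over the 3 ages, percentile 71.1). It was -0.0542, -0.0111 and 0.107 at 3, 4 and 5 months (percentiles 16.4, 40.0 and 97.7), and so ran with the mitochondrial list at 5 months only. None of the 40 passed by limma in either comparison. Reads from nuclear copies were not tested, and neither was any biological cause.

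Chance was examined by other splits of the libraries into groups of the same size. For KO minus WT in T, 1 of 10 splits gave as many genes as the real 1, the real split itself, and the highest other gave 0; 10 splits are too few for a share under 0.05. In N, 2 of 10 gave as many as the real 1, and the highest other, 8 genes, put the N libraries of 3 months with the WT library of 5 months. Again 10 splits are too few, but that split points to a structure of the samples by age. Only 4 of the splits, the real one included, keep 1 library of each age in each group. Among these the highest other gave 0 genes in T and 0 in N, and they too are too few. For T minus N, 1 of 10 splits gave as many as the real 5612 genes in WT and 1 of 10 as many as the real 4651 in KO, with 0 as the highest other in each, and 10 splits are too few there too. For the interaction the real count was 0, which all 100 of the 100 drawn splits reach by construction (highest 2), so this count says nothing about chance. For 4 minus 3 months, 3 of 35 splits gave at least the real 5 genes, the real split among them, so chance is not excluded. The highest, 1347 genes, parted the T libraries by age and the N libraries by genotype, which points to a structure of the samples. That split keeps the real ages in T, so it carries any age difference of T and is no pure measure of chance.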

How the results depend on the processing

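The voom fits and, for the lists, leaving out the KO N library of 3 months and the age block within tissue were chosen after the results were seen; the other alternatives were planned. Where the count moved, the cause was not tested unless stated.

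Cul4b kept its direction under all 27 alternatives in each tissue. It was the 1 gene that passed in KO minus WT in T, and that count became 0 with a pseudocount of 0.1 (limma adjusted p of Cul4b 0.068), 0 with no replicate block for age (0.20), 0 with the age block within each tissue (0.16), 0 in the model of only the 2 groups (0.27), which has fewer libraries, and 0 to 1 when single libraries or ages were left out; over all alternatives the adjusted p ranged from 0.0076 to 1. With no filter on low values 1 gene passed in T, and it was not Cul4b (adjusted p = 0.056). In N the count of 1 became 3 with no filter, 0 with only the 2 groups (limma adjusted p of Cul4b 0.90, in a range of 0.0025 to 0.949) and 0 to 2 in the leave-outs.

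For T minus N in WT the 5612 genes became 3383 with a filter at a mean of 5 FPKM (fewer genes tested), 9210 with TPM rescaling, 8462 when rescaled without mitochondrial and immunoglobulin genes, 3708 without the age block, and 2461 to 5926 in the leave-outs. For KO the 4651 became 2720, 7591, 7124 and 2954 under these alternatives, 1916 with only the 2 groups (fewer libraries), and 1997 to 4592 in the leave-outs. Under TPM rescaling the Y-linked genes reversed in WT to 0.14 for Uty, 0.23 for Ddx3y and 0.10 for Eif2s3y, and without mitochondrial and immunoglobulin genes to 0.0336 for Uty and 0.11 for Ddx3y; the shift of the median gene, 0.76 and 0.67, exceeds these values. Scaling recovered reads by their sums in voom moved the WT genes to 6668 up and 1504 down, and the KO genes to 5326 and 1475.

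The interaction count of 0 became 1 with no filter and stayed 0 in the leave-outs. For 4 minus 3 months the 5 genes became 0 with no filter, 9 with the filter at 5 FPKM, 8 with TPM rescaling, 3 without mitochondrial and immunoglobulin genes, 0 in the table of 3 and 4 months alone (fewer libraries), 1 with either voom fit, and 0 to 4 in the leave-outs. Treating T and N as 1 animal gave 3851, where the correlation between T and N enters the model although T and N libraries of 4 months did not pair. A model without the age block has no value for this comparison, and a model of only the 2 groups has none for the interaction.

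With an estimated correlation 0 lists passed in any of the 5 list comparisons. Wnt, colonocyte, goblet cell and MDSC lists were among those passing by fry for T minus N in WT (fry adjusted p = 0.00053, 0.00012, 0.00012 and 0.00077). In KO they passed as well (0.00042, 0.00015, 0.00015 and 0.0017). For KO minus WT in T the lowest fry adjusted p was 0.157, and MDSC markers stood at 0.99. In N only the CRL4 ligase list, which holds Cul4b, passed by fry (0.0037, next lowest 0.82). The lowest for the interaction was 0.49. The 7 lists of KO minus WT in T, 1 up and 6 down, became 7 to 11 in the leave-outs; without the 5-month libraries they were again 7, but 5 up and 2 down, with 3 shared. In the leave-outs the 10 in N became 3 to 13, the 14 and 13 of T minus N became 11 to 18 in WT and 12 to 16 in KO, and the 10 of the interaction became 1 to 11. Genes at least 2-fold apart at all 3 ages were 5 in T and became 23 with a pseudocount of 0.1 and 3 with the filter at 5 FPKM; in N the 10 became 49 and 5.

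Among named genes that passed, 86 in WT T minus N gave 2304 values, of which 2116 kept their direction and passed, 183 no longer passed and 5 reversed. The 80 in KO gave 2145, of which 1956 kept both and 189 no longer passed. Hoxa11os passed in 5 of 22 alternatives and kept its direction in all. The depth of 18263611 to 25321931 reads per library limits genes below about 0.0524 to 0.1002 FPKM.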

Other observations

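All tests in this part were chosen after the results were seen.

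Some of the homeobox genes that mark position along the gut differed between N and T. Cdx2 ranged from 54.5 to 121 FPKM in the 6 N libraries and from 0.561 to 2.43 FPKM in the 6 T libraries, and fell by 5.29 in WT and fell by 4.99 in KO (limma adjusted p = 2.3e-05 and 3.3e-05). Of 9 Hox genes of groups 4 to 8, 6 fell in T in each genotype. Of 8 Hox genes of groups 10 to 13, 1 rose and 1 fell in WT, and 3 rose and 0 fell in KO by limma. The posterior gene Hoxb13 was 28.0 and 59.3 FPKM in the N libraries of 3 months (WT and KO), 1.23 to 3.598 FPKM in the 4 other N libraries, and 28.2 to 72.3 FPKM in T, and its T minus N difference did not pass (limma adjusted p = 0.058 in WT and 0.091 in KO). Hoxd13 rose by 3.23 in WT T and 4.06 in KO T (limma adjusted p = 0.0034 and 0.0014).

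A different position of the N pieces along the colon could add to the rise of Wnt targets and the fall of colonocyte and goblet cell genes in T. Scaling between tissues as the whole cause is argued against. Rescaling to equal sums per library shifted the median gene by 0.76 in WT and 0.57 in KO, and all 6 list medians kept their direction. The smallest of them, that of goblet cell genes in WT, fell by 2.51 (SE 0.29 over the 3 ages), and Wnt targets stood at 3.16 and 3.02. Position stays open. The list medians at 3 months were on average 0.939 of those at 4 and 5 months (SD 0.212, range 0.731 to 1.30 over 3 lists in 2 genotypes). That would count against position only if N and T were matched at 3 months, and they were not. Hoxb13 came nearest, with log2 T minus N differences of 0.54 in WT and -1.05 in KO. Hoxd13 was 1.34 and 3.20 FPKM in N against 12.1 and 20.8 FPKM in T (WT and KO), and Cdx2 93.2 and 54.5 FPKM against 1.29 and 2.43 FPKM. Whether the remaining difference stems from tumor formation was not tested beyond this.

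The Cul4b reads left in KO libraries may come from cells other than epithelium, which keep the gene. Over the 6 KO libraries, Cul4b correlated with the mean of 70 stromal and immune genes at rho = 0.60 (exact permutation p = 0.24) and r = 0.66 (exact permutation p = 0.16), and at r = 0.22 without the 2 libraries farthest from the median. The relation did not pass, so the source stays open.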
